A study of Mus musculus with 64 samples.

How the data were processed

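RNA of 3T3-L1 adipocytes, a mouse fibroblast line differentiated in culture into fat cells, was measured on 64 spotted arrays with 2 colours. Per the labels, the RNA of each culture was labelled with Cy5, and a pool of RNA from untreated differentiated 3T3-L1 cells was labelled with Cy3 on every array, from 20 µg of total RNA. The titles name 22 vehicle arrays, 21 TNF arrays and 21 arrays of TNF with ASA and TGZ, here called the combination, and each array was grouped by its title. The series' design text says that the replicates were grown and harvested independently. The labels speak of 6 collection days and 5 passage numbers and do not tie them to arrays, so neither was entered in a fit.

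The labels conflict on the vehicle arrays. Their titles and the design text call them vehicle, while the source text of the same arrays describes 48 h with TNF before 24 h in medium with albumin. Whether these cells received TNF in the first 48 h is therefore not settled, and "vehicle" is used here as the title's name. The labels also leave open whether TNF was present with ASA and TGZ in the last 24 h. The titles join the 3 names and the protocol speaks of co-treatment, while the agents listed for that step are ASA and TGZ without TNF.

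The deposited values were taken as log2 ratios of 6963 features, with at most 2 decimals and no missing value (0). The base of the log, the background correction and the normalization are not given in the sources used here. Values ran from -3.48 to 4.16. Base 10 would make the highest value a ratio of 14450, base e 64.1 and base 2 17.9, and base 2 was assumed for any fold. Sizes are otherwise given in deposited log units. The dyes in the labels make sample over pool the likely direction of the ratio. If the deposited ratio was turned, every higher below is a lower and the counts stay as they are. Whether features were filtered before deposit is not stated.

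The median of an array lay between -0.04 and 0.07 in the vehicle group, between -0.05 and 0.02 in the TNF group and between -0.06 and 0.02 in the combination group. The values of each feature appear to have been centred on the vehicle arrays. A weighted mean of the 22 vehicle arrays was nearly constant across features, with a variance of 0.000861 against 0.0136 for the next such combination, a ratio of 15.8. The same ratio was 1.21 for the TNF arrays and 1.09 for the combination arrays. Such centring shifts all groups alike and leaves differences between groups as they were, while levels against the pool cannot be read. It also lowers correlations between vehicle arrays, whose median r was -0.0586 against 0.642 within TNF and 0.586 within the combination. Of the 2016 pairs of arrays, 33 had r under -0.3, and all 33 included a vehicle array. The lowest was -0.707, between vehicle array 6 and combination array 13. The direction was kept because the labels state the dyes and it remains likely rather than settled. No 2 arrays were identical (0 pairs).

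Features carry plate and well positions as identifiers. None of them (0 of 6963) matched the gene table, and no table pairing them with genes was used here. Gene names are therefore not given, and the 26 gene lists chosen beforehand could not be tested. The rule for named genes, fixed before the data were examined, took those with the largest rises and falls among features at an adjusted p under 0.05 with 1 gene symbol, a fixed set of genes and examples from the lists. Without symbols it was reduced to the features with the 2 largest rises and the 2 largest falls in each of the comparisons TNF against vehicle and combination against TNF. The planned averaging of rows of 1 gene was likewise not possible, and each feature was tested alone.

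Group means were fitted to all 64 arrays at once with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with no block. This fit took the arrays of a group as independent. Some arrays of a group deviated together after group means were removed, with r up to 0.816 within the combination group. Every SE and p-value from this fit rests on that assumption, so the p-values may be too small. Deviations shared by arrays of different groups can instead make them too large. With the replicate number as a block, 4441 features differed between TNF and vehicle, against 4111 without it. For the combination the counts were 2038 and 1724 against TNF, and 4593 and 4232 against vehicle. Collection day and passage could not be entered to test the assumption. P-values are two-sided and adjusted by Benjamini-Hochberg over the 6963 features within a comparison, with a threshold of 0.05. The fit was tested on simulated data for TNF against vehicle, with independent noise and 200 of 6963 features changed. It recovered 47% of 100 features changed by 0.25 log units and 95% of 100 features changed by 0.5, with 1.39% false calls. The real arrays were not independent and far more features were called, so these rates do not describe the real counts. Array checks used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9. Scanner intensities were not used here, so signal over background is unknown and the number of arrays limits the precision.

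The comparisons TNF against vehicle and combination against TNF share the TNF arrays, which alone pushes their differences in opposite directions. Their relation was recomputed in 100 permutations of arrays with group means removed and in 100 random divisions of the TNF arrays into 10 and 11. Permutations within the replicate numbers and random divisions of the vehicle arrays, which the comparisons against vehicle share, were added after seeing the data. Alternatives fixed beforehand covered the scaling of arrays, a variability filter, the prior, array weights, a block on the replicate number, the arrays in the fit, the threshold, a test against a minimal difference, odd and even numbers, and leaving out each array. Alternatives added after seeing the data covered a division of the replicate numbers into 1 to 11 and 12 upwards, well rows, arrays with a wide spread and merged features.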

Results

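The arrays addressed what TNF, an inflammatory cytokine used to make cultured fat cells insulin resistant, did to transcript levels in 3T3-L1 adipocytes, and what a later treatment with ASA and TGZ did. The abbreviations are the labels' own and were read as acetylsalicylic acid (aspirin) and troglitazone, a thiazolidinedione that activates PPARγ. Adipocytes between days 8 and 12 of differentiation received TNF at 3 ng/ml for 48 h, and then for 24 h either TNF again at 3 ng/ml or 5 mM ASA with 10 µM TGZ. The labels do not settle whether TNF stayed in the medium with ASA and TGZ, so in the comparison of the combination with TNF the addition of the drugs and the removal of TNF cannot be told apart. The vehicle cultures spent the last 24 h in medium with 0.2% albumin, which is listed for this group alone. The labels conflict on whether these cultures had received TNF before. If they had, TNF against vehicle compares continued TNF with its withdrawal. Features described below as changed, raised or lowered by TNF are those that differed in this comparison, whatever the cause. The groups held 22 vehicle, 21 TNF and 21 combination arrays. The SD of the 6963 values of an array had a median of 0.217 log units in the vehicle group, 0.416 in the TNF group and 0.441 in the combination group, where the apparent centring on the vehicle arrays by itself narrows the vehicle values.

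Differences between TNF and vehicle were widespread. Of 6963 features, 4111 (59.0%) differed between TNF and vehicle at an adjusted p under 0.05 in limma, 1883 higher and 2228 lower under TNF. The count was 3055 with arrays scaled to a common MAD, 3148 after quantile normalization and 3238 at an adjusted p of 0.01. Most of these differences were small, with a median of 0.324 log units among the higher features and -0.301 among the lower. A difference of at least 0.5 was reached by 655 changed features, of which 419 were higher and 236 lower. A difference of at least 1 was reached by 60, of which 38 were higher and 22 lower. The balance of higher and lower features depended on the scaling, with 2059 higher and 1997 lower when each array was centred on its median, 1602 and 1453 with a common MAD, and 1504 and 1644 after quantile normalization. When the test was set against a 1.2-fold difference, 737 features passed, 433 higher and 304 lower.

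The largest rise under TNF was that of feature MSK10c19, from 0.0909 ± 0.420 (SD, n = 22) in vehicle to 2.44 ± 0.836 (SD, n = 21) in TNF. The difference was 2.35 (SE 0.176, adjusted p = 5.98e-18 in limma), which is 5.10-fold at base 2, and 20 of the 21 TNF arrays lay above the vehicle mean. Feature MSK03a16 differed by 2.25 (SE 0.128, adjusted p = 7.44e-24 in limma), with 21 of 21 TNF arrays above the vehicle mean. The largest falls were those of MSK13m2, with a difference of -1.39 (SE 0.163, adjusted p = 1.38e-10 in limma), and of IRchip2Aj6Pob, with -1.37 (SE 0.188, adjusted p = 9.39e-09 in limma). All 21 TNF arrays lay below the vehicle mean for both.

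**Figure D1:**
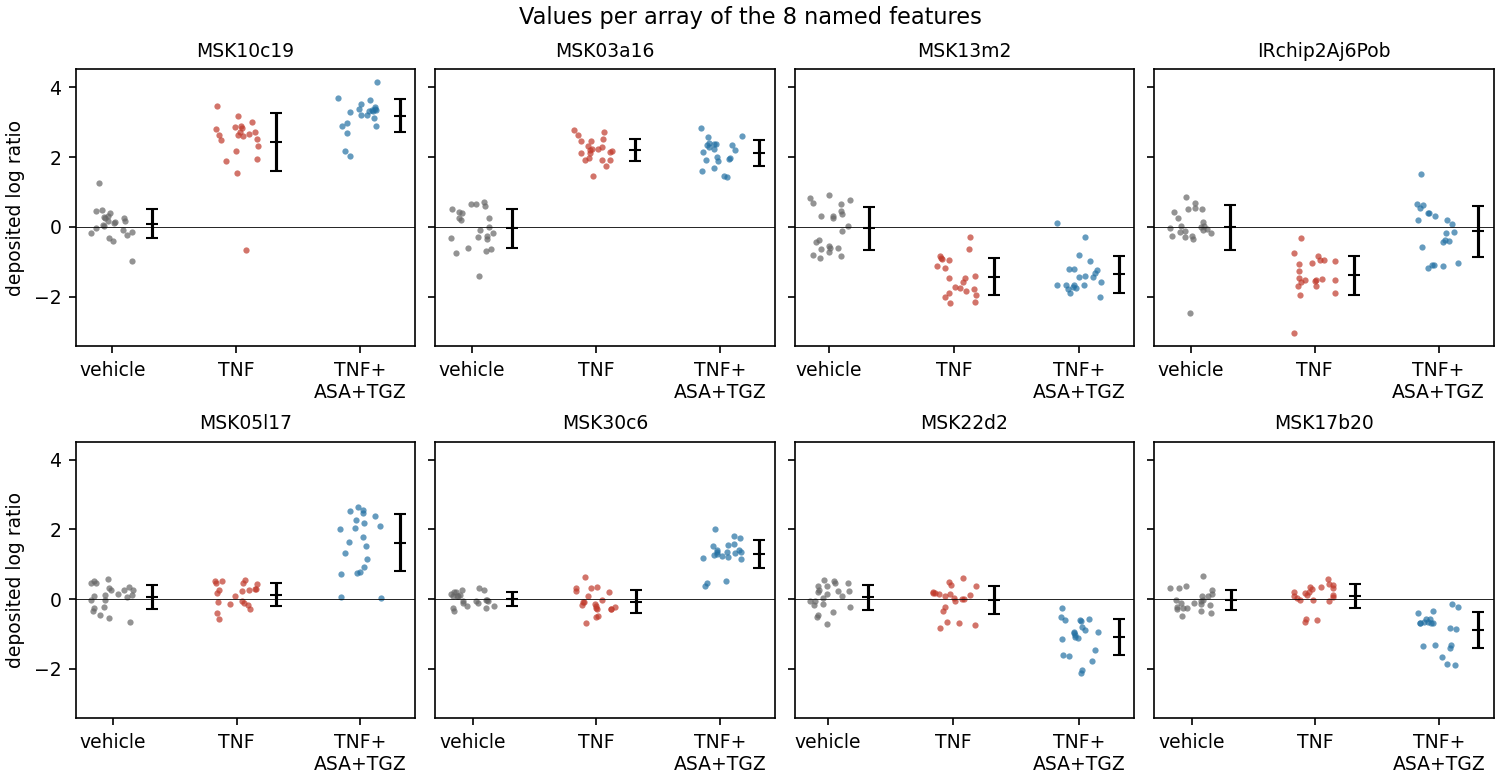
Deposited log ratio (vertical axis) of the 8 named features on each array, by group (horizontal axis). Points are arrays (22 vehicle, 21 TNF, 21 combination), and bars give the mean ± SD. The upper panels hold the features with the largest differences between TNF and vehicle, and the lower panels those with the largest differences between the combination and TNF.

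The combination changed fewer features relative to TNF than TNF did relative to vehicle. Between the combination and TNF, 1724 of 6963 features (24.8%) differed, 838 higher and 886 lower in the combination. The numbers were 881 and 862 with each array centred on its median, 597 and 702 with a common MAD, 612 and 737 after quantile normalization, and 542 and 682 at an adjusted p of 0.01. The median difference was 0.320 log units among the higher and -0.362 among the lower. At least 0.5 was reached by 240 features, 100 higher and 140 lower, and at least 1 by 18, of which 17 were higher and 1 lower. The test against a 1.2-fold difference passed 159 features.

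Among the features with the 2 largest rises and the 2 largest falls between the combination and TNF, MSK05l17 differed by 1.48 between the combination and TNF (SE 0.161, adjusted p = 3.37e-11 in limma), with 19 of 21 combination arrays above the TNF mean. Its difference between TNF and vehicle was 0.0666 (adjusted p = 0.75 in limma). Feature MSK30c6 differed by 1.37 (SE 0.0966, adjusted p = 1.19e-18 in limma), with 21 of 21 arrays above the TNF mean. The falls of MSK22d2, -1.06 (SE 0.128, adjusted p = 9.6e-10 in limma), and of MSK17b20, -0.981 (SE 0.117, adjusted p = 5.29e-10 in limma), were seen in 21 of 21 combination arrays each. None of these 4 passed the test between TNF and vehicle.

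Features fell into groups by the pair of comparisons. Features higher in TNF than in vehicle and lower in the combination than in TNF numbered 530, and 239 were lower and then higher. These 769 opposed features were 18.7% of the features that differed between TNF and vehicle, with 28.2% of those higher in TNF and 10.7% of those lower. Independent lists of these sizes would share 239.6 and 268.1 features, so only the first kind lay above that number. These numbers take features as independent, although many moved together, and 139 of the 530 belonged to a single set of linked features described below. The directions were not counted separately with the TNF arrays divided. Of the 769, 496 no longer differed from vehicle past the threshold, 168 still lay on the side of TNF and 105 lay on the other side of vehicle. Another 218 features moved further the same way, 99 up and 119 down, against 510.1 for independent lists. Opposed and same-way features numbered 462 and 99 with a common MAD, 490 and 87 after quantile normalization, 441 and 101 at an adjusted p of 0.01, and 18 and 7 against a 1.2-fold difference.

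The opposed features share the TNF arrays between both tests. With no effect in the data, 100 permutations gave 0 opposed features, a value that says little because a feature must pass both tests. With the TNF arrays divided between the tests, 443 features were opposed (median of 100 divisions, range 312 to 551), against 299.6 for independent lists. In the same divisions 129 features moved further the same way (median, range 74 to 265). The correlation of the 2 sets of differences across features, which are not independent replicates, was -0.236 with shared arrays. It was -0.490 with no effect (median, range -0.800 to 0.0286), a range that holds the observed value and is -0.776 to -0.0597 when arrays were permuted only within replicate numbers. It was -0.189 with the arrays divided (median, range -0.374 to 0.0160). The covariance was -0.0165, against a median of -0.00327 with no effect (range -0.0108 to 0.000199, and -0.00634 to -0.000336 within replicate numbers), a difference of -0.0132. The observed -0.0165 lay below both of these ranges, which were likewise computed with shared arrays. With the arrays divided the covariance was -0.0138 (median, range -0.0239 to 0.001375), a range that reaches past 0. No range with no effect was computed for divided arrays, so the divided value has none to be set against.

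**Figure D2:**
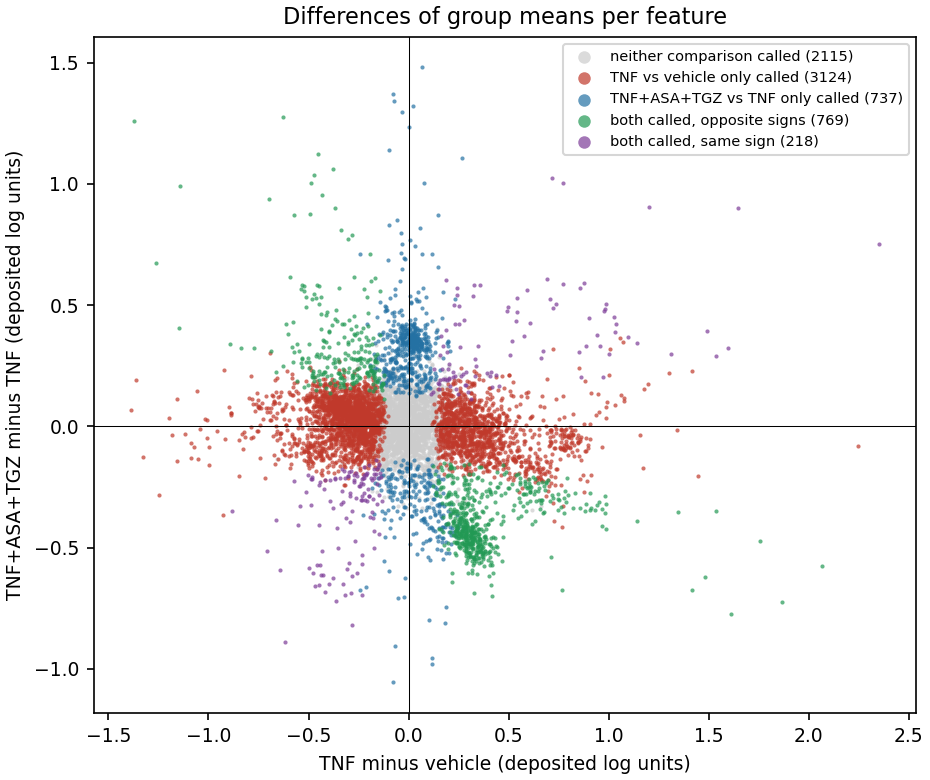
Difference between TNF and vehicle (horizontal axis) and between the combination and TNF (vertical axis) for each of 6963 features, in deposited log units. Points are features, coloured by which comparison passed an adjusted p of 0.05. The 769 opposed features lie in the upper left and lower right and the 218 that moved further the same way in the other corners.

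Feature IRchip2Aj6Pob belonged to the opposed features. It fell by 1.37 under TNF, was 1.26 higher in the combination than in TNF (SE 0.190, adjusted p = 3.42e-07 in limma), and differed from vehicle by -0.116 (adjusted p = 0.598 in limma). Feature MSK10c19 moved further the same way, with a second rise of 0.751 (SE 0.178, adjusted p = 0.00077 in limma). MSK03a16 and MSK13m2 did not pass the test between the combination and TNF, with differences of -0.0795 (adjusted p = 0.736 in limma) and 0.0686 (adjusted p = 0.829 in limma).

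Of the 4111 features changed by TNF, 3048 (74.1%) also differed in the same direction between the combination and vehicle. Both tests share the vehicle arrays, which alone favours the same direction. With the vehicle arrays divided into 11 and 11, the share was 65.4% (median of 100 divisions, range 54.2% to 76.5%), with 2204 features against 854.9 for independent lists. The correlation of the differences across features was 0.799 with shared arrays, 0.746 with the arrays divided (median, range 0.667 to 0.806) and 0.536 with no effect (median, range -0.0484 to 0.810), a range that holds the observed value. The covariance was 0.0900 with shared arrays, 0.0866 with the arrays divided (median, range 0.0812 to 0.0902) and 0.00334 with no effect (median, range -0.000261 to 0.00996). In all, 4232 features (60.8%) differed between the combination and vehicle, 2008 higher and 2224 lower, and the test against a 1.2-fold difference passed 782. This balance turned to 2174 higher and 1912 lower with each array centred on its median, 1769 and 1321 with a common MAD, and 1608 and 1527 after quantile normalization. At least 0.5 was reached by 717 and at least 1 by 115. The largest difference was that of MSK10c19, at 3.10 log units (SE 0.176, adjusted p = 3.6e-24 in limma).

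The arrays numbered 1 to 11 and those numbered 12 upwards differed in every group, a division found by looking at the data. The comparisons were therefore repeated within each part. TNF against vehicle gave 3477 features in the first part and 2627 in the second, with r = 0.884 between the differences across features. The combination against TNF gave 1064 (391 higher, 673 lower) and 884 (471 higher, 413 lower), with r = 0.743. A limma test of the difference between the parts called 1 feature in this comparison, with 324 at an unadjusted p under 0.05. The same test called 19 features for TNF against vehicle and 18 for the combination against vehicle, with 357 and 485 at an unadjusted p under 0.05. With no difference between the parts, a share of 0.05 of the 6963 features would be expected at such an unadjusted p. The unadjusted numbers are therefore not counts of features that differed. The combination against vehicle gave 3318 and 2911, with r = 0.880. In the same order, 2118, 508 and 2083 features passed in both parts. For features chosen as changed by TNF in one part and measured in the other, the median difference between the combination and vehicle was 81.9% to 88.9% of that between TNF and vehicle. Both differences use the same vehicle arrays, and with these divided at random the ratio ran from 60.7% to 134.7%, so its size is not well determined.

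**Figure D3:**
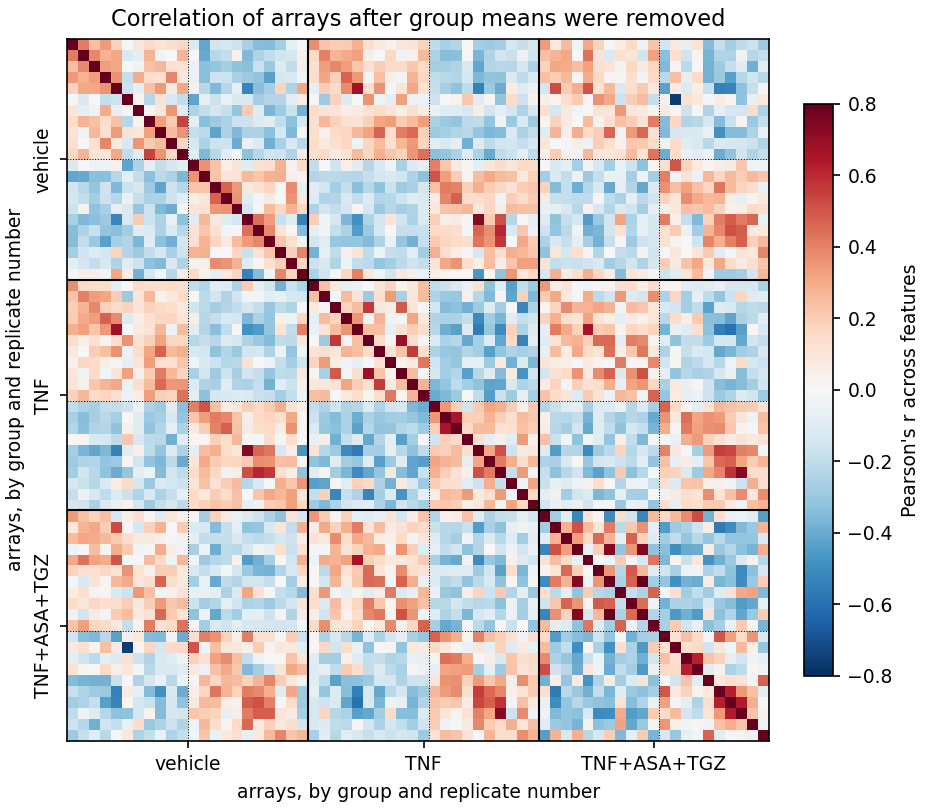
Pearson's r across 6963 features between all pairs of the 64 arrays, after the mean of each group was removed, with arrays on both axes ordered by group and replicate number. Solid lines separate groups and dotted lines separate numbers 1 to 11 from 12 upwards. Arrays of the same part tend to correlate above 0 and arrays of different parts below 0.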

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

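The division of the replicate numbers, the arrays left out by name, the well-row correction, the turned sign and the merged features were chosen after seeing the data; the other settings were fixed before the data were examined. Named features kept sign and call in 171 of 171 values over 22 settings, and no feature called over all arrays was called in the opposite direction. The 8 named features had been chosen for the largest differences in these same arrays. Their kept calls therefore say little about the other features.

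Opposed and same-way features numbered 462 and 99 with a common MAD, 490 and 87 after quantile normalization (correlation -0.369), and 441 and 101 at an adjusted p of 0.01. Against a 1.2-fold difference the 3 comparisons gave 737, 159 and 782 features, with 18 opposed and 7 same-way. Odd numbers gave 2416 for TNF against vehicle, 296 opposed, 79 same-way and a correlation of -0.156. Even numbers gave 600 for the combination against TNF, 2539 for the combination against vehicle, 287, 50 and -0.363. Numbers 1 to 11 gave 1064 for the combination against TNF, 508 opposed and 94 same-way. Numbers 12 upwards gave 2627 for TNF against vehicle, 884 for the combination against TNF, 219 opposed and 65 same-way. Merged features left 144 same-way. A common MAD and quantile normalization give all arrays the same spread. As deposited, the median SD was 0.217 in vehicle, 0.416 in TNF and 0.441 in the combination. These 2 settings therefore tend to widen vehicle values and to shrink those of the other groups. How much of the change in counts comes from this was not tested.

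Leaving out each array gave 3988 to 4215, 1645 to 1792 and 4141 to 4378 features in the 3 comparisons, 715 to 794 opposed, 194 to 224 same-way and correlations of -0.265 to -0.214. With the replicate number as a block the counts were 4441, 2038, 4593, 940 and 271. Same-numbered arrays tended to deviate together, with r over 0.1 in 19, 17 and 18 of 21 pairs (16, 14 and 16 after part means were removed), and 11, 6 and 12 correlated best with their own number. Not every pair did, and the labels state no pairing, so the numbers were not treated as pairs.

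Filters on missing values and a test row by row repeat the values as reported, and gene list settings were not run. Signal over background is unknown.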

Other observations

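All tests in this part were chosen, and their bounds written, after the results they measure had been seen or explored, the counts over random splits included.

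Random splits of the arrays into groups of the same sizes gave fewer features than the real groups in all 3 comparisons. This argues against a chance division of the arrays as the source of counts of this size. The splits took arrays as exchangeable, although same-numbered arrays and arrays of the same part tended to deviate together. For opposed and same-way features the splits say little, because a feature must pass both tests. In each of the 5 cases 1 of 100 splits, the real one, reached the real count. The real counts were 4111, 1724 and 4232 for the 3 comparisons, 769 for opposed and 218 for same-way features, and the highest of the other splits gave 1327, 226, 95, 11 and 0.

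Every group shifted between replicate numbers 1 to 11 and 12 upwards. This division was found by scanning 17 places to divide the numbers. It accounted for 18.5% of the variance within groups, while the highest share when numbers were permuted within groups and the scan repeated was 10.9% (p = 0.001, the smallest that 1000 permutations can give). The shift of a feature in vehicle correlated with that in TNF at r = 0.762 across features, in line with a component shared by all arrays of a part, and the well row, read from the feature's identifier, accounted for at most 14.4% of its variance, which argues against the well row as the whole cause. Collection day, passage and a print or labelling batch stay open and were not tested, since the labels do not tie them to arrays. With the part as a block the 3 comparisons gave 4306, 1848 and 4424 features.

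A pair of vehicle arrays had a spread far above the group's median SD of 0.217. The well row accounted for over 20% of the variance on 4 vehicle, 2 TNF and 0 combination arrays, and with well-row means removed the 3 comparisons gave 4388, 1905 and 4527 features. For array 17, with an SD of 0.593, it accounted for 67.4% of the variance, against at most 0.468% with wells permuted, so a well-row effect of printing is a candidate explanation. For array 6, with an SD of 0.600, the row accounted for 1.59%, and its r of -0.370 with the mean TNF profile argues against a TNF sample under a vehicle label. Array 6 mirrored combination array 13, the widest of all with an SD of 0.626, at r = -0.758 after group means were removed, where the next lowest pair had -0.599. With its sign turned array 6 had r = 0.707 with combination array 13. Its r with the combination mean was then 0.308, where the lowest combination array had 0.611 with the mean of the others. Whether array 6 is a turned hybridisation of the RNA of combination array 13 cannot be told apart from other causes. The centring on the vehicle arrays alters such r values, and no intensities were used here. The 3 comparisons gave 4082, 1852 and 4445 features without vehicle arrays 6 and 17, 4029, 1799 and 4266 without vehicle array 6 and combination array 13, and 3716, 1740 and 4150 with the sign of vehicle array 6 turned, where 596 features were opposed.

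Many features on different plates moved together. Links of r over 0.9 across arrays gave 12 sets of at least 20 features, with 889 features in all (12.8%), and the median r between members was 0.799 in set 1 and 0.792 in set 2. Set 1 held 220 features on 26 plates that differed by 0.349 ± 0.0420 (SD over features) between the combination and TNF and held 42.2% of those higher there and not called between TNF and vehicle, while set 2 held 155 and 26.2% of the features raised by TNF and then lowered. In sets 1 and 2 the SD of members' slopes on their set was at most 1.18 times that of 24 neighbouring wells that behave like repeats, which may reflect 1 signal read by many spots, and this ratio ran from 0.903 to 3.90 in the other sets. By correlation, members of both sets agreed less than those 24 wells, whose median r was 0.921. At most 10.5% of either set lay in 1 well row, which argues against the well row as the cause for these sets, while set 7, not tested, had its 45 features in 4 of 16 rows. The largest plate held 16 of the 220 and 12 of the 155 features, so no single plate makes up either set, although members were unevenly spread over plates (permutation p = 0.0147 and 0.0067). Co-regulated genes of like amplitude stay open too, since no gene names were used and the sets were chosen by correlation; merging linked features left 5815 features, with 3277, 1169 and 3301 changed and 551 opposed.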
